A study of Mus musculus with 5 samples.

How the data were processed

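RNA was measured in 5 libraries of the mouse melanoma line B16F10, 1 library for each of 5 groups: conventional 3D culture, dynamic suspension culture, shControl, HIF-1α knockdown and HIF-1α overexpression. Per the labels' protocols, 3 repeats of each culture were pooled into 1 library, made by poly(A) selection with a strand-specific kit from RNA of integrity number over 7.0, with inserts near 300 bp, and sequenced as paired 150 bp reads on a NovaSeq instrument. Per the submitters' processing notes, cutadapt, HISAT2 and StringTie were used with the builds GRCm38.p6 and mm10. The role of each tool, the program that counted the reads and its annotation are not given in the sources used here.

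Values per Ensembl gene were used as deposited. The deposited values of the libraries labelled knockdown and overexpression are counts, whole numbers whose frequency falls steadily from 1 to 10. The deposited values of the conventional 3D, dynamic suspension and shControl libraries are estimated counts by their pattern: low values pile up at 4 and 8, and 28.1%, 29.2% and 26.8% of the low values are multiples of 4, against 16.1% and 17.3% in the plain counts. The sum of the values, used here as depth, was 61267892, 61014260 and 59493240 for conventional 3D culture, dynamic suspension and shControl. It was 14803426 and 15393189 for the libraries labelled knockdown and overexpression. Estimated and plain counts may not be in the same unit, so these sums do not show how far sequencing depth differed. All 54100 gene identifiers matched the GENCODE M21 annotation of GRCm38, from which names and coordinates were taken. Every column was assigned to a sample by the sample descriptions, with 0 left over. The headers were B3 for conventional 3D culture, B4 for dynamic suspension, B5 for shControl, B16F10 for knockdown and B16F10Q for overexpression. The header B16F10 is the bare name of the line and does not name a knockdown.

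Each library was scaled by TMM factors from edgeR 4.0.16 over all 5 libraries (0.869 for conventional 3D culture, 0.99 for dynamic suspension, 1.035 for shControl, 1.029 for the library labelled knockdown and 1.091 for the library labelled overexpression), in R 4.3.3. The log2 ratio of TMM-scaled CPM was taken between 2 libraries with a prior count of 2. The exact conditional binomial (Clopper-Pearson) 95% interval of the ratio of the 2 counts covers counting error only. For estimated counts it is approximate and may be too narrow. A gene was called beyond 2-fold when its log2 ratio was at least 1 in size, its mean over the 2 libraries was at least 1 CPM and the interval excluded a ratio of 1. With 1 library per group no test across conditions was run and no p-values are given. For a gene with 0 counts the ratio is a bound from a floor of 3 counts, which is 0.056 CPM in conventional 3D culture, 0.05 in dynamic suspension, 0.049 in shControl, 0.197 in the library labelled knockdown and 0.179 in the library labelled overexpression. Genes with 1 to 3 counts are given with the ratio of scaled values without prior and its interval.

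The planned comparisons, named here by the labels, were dynamic suspension against conventional 3D culture, knockdown against shControl, overexpression against shControl, and overexpression against knockdown. All 10 pairs of libraries were also compared, with Spearman rho across genes. The ratios of the libraries labelled knockdown and overexpression against shControl were crossed by direction, beside the counts expected for independent lists and the mean of 100 simulated sets of unchanged libraries (Poisson counts at the shControl proportions).

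In total 29 gene lists were fixed before the data were examined. They cover HIF pathway components, HIF-1 glycolytic targets, other HIF-1 and hypoxia targets, p53 targets, p53 and its regulators, stemness markers, melanocyte differentiation, cell cycle and DNA replication, cholesterol synthesis, the integrated stress response, unfolded protein response chaperones, interferon response and antigen presentation, extracellular matrix, YAP and TEAD targets, NF-kappaB inflammatory genes, apoptosis regulators, NRF2 antioxidant genes, immediate early genes, heat shock genes, lysosome and autophagy, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal protein genes and histone genes, and markers of immune cells, fibroblasts, endothelium, epithelium and erythroid cells. Members with a mean of at least 1 CPM over the 5 libraries count as measured. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on expression in 20 bins, and lists below percentile 2.5 or above 97.5 lie outside that range. This describes the libraries compared and is no test of a condition.

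Genes to name were chosen by a rule fixed before the data were examined. It takes Hif1a, Epas1, Trp53, Mdm2 and Cdkn1a throughout; the 8 highest and 8 lowest genes with a mean of at least 10 CPM in each of the first 3 comparisons, without predicted genes; up to 4 members of each list described, at 5 CPM or more, by size of ratio; and the 10 genes with the largest opposite ratios. Some genes that the rule chose are not reported here. Values of other genes are printed only for the patterns weighed at the end and were chosen after they were seen.

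After the data were examined, a set of 16493 genes of own sequence among 21864 protein-coding genes was added. At most 10% of such a gene's exons overlap another gene, on either strand, and at most 20% of its 31-mers occur in another gene. The same rule chose the lowest and highest genes again within it. Also added after the data were examined were the estimated counts divided by 4 and the dynamic suspension library as the reference. The alternatives planned beforehand were DESeq2 1.42.0 size factors, total counts, prior counts of 0.5 and 8, no CPM filter, a mean of at least 10 CPM, and limits of 1.5-fold and 4-fold.

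The scripts were tested on simulated data before use, with 200 changed genes at the real means and library sizes. The changed genes were drawn from those at 5 CPM or more in the reference library, and all counts were Poisson. Recovery between 1 and 5 CPM and the difference between the kinds of column were therefore not tested. For dynamic suspension against conventional 3D culture 100.0% of 100 genes changed 3-fold and 100.0% of 100 changed 8-fold were recovered, with 0 false calls among 12531 genes tested. The same 100.0% was recovered at both sizes for the library labelled knockdown against shControl (8 false calls of 12877), overexpression against shControl (4 of 12884) and overexpression against the library labelled knockdown (13 of 11996). Other tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.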

Results

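Transcripts were measured by strand-specific, poly(A)-selected RNA sequencing in 5 libraries of B16F10, a pigmented mouse melanoma cell line. Each of the 5 groups had 1 library: conventional 3D culture, dynamic suspension culture, an shControl line, and lines labelled HIF-1α knockdown and HIF-1α overexpression. HIF-1α is the oxygen-regulated subunit of the transcription factor that drives the response to low oxygen. By its title and design text, the series asks how this factor relates to stem-like tumour cells and to the p53 pathway, and compares ways of enriching such cells. The labels give all 5 samples the same growth protocol, serum-free medium on a shaker at 60 to 80 rpm for 7 to 10 days, so how the cultures differed is known from the sample titles alone. Each library pooled 3 repeats before sequencing. With 1 library per group, no difference has a replicate check, and each comparison is between 2 libraries.

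The deposited values summed to 61267892 in the conventional 3D library, 61014260 in dynamic suspension and 59493240 in shControl, against 14803426 and 15393189 in the libraries labelled knockdown and overexpression. The first 3 columns hold estimated counts, in which low values pile up at 4 and 8, and the other 2 hold plain counts. Genes at a value of 4 outnumbered those at 3 in the conventional 3D column (796 against 412), whereas in the column of the library labelled knockdown they were fewer (422 against 580). Annotated pseudogenes took 4.81%, 4.0% and 3.44% of the values in the conventional 3D, dynamic suspension and shControl columns and 0.92% and 0.71% in the columns labelled knockdown and overexpression. In both comparisons with shControl, the kind of column and the group therefore cannot be told apart. Genes marked "shared sequence" in the text overlap another gene's exons or share sequence with another gene, and their values are uncertain. A count of 0 allowed up to 3 counts, or 0.049 to 0.197 TMM-scaled CPM depending on the library. Intervals and this floor cover counting error only. For the estimated counts they are approximate and may be too narrow, since low values pile up at 4 and 8.

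**Figure D1:**
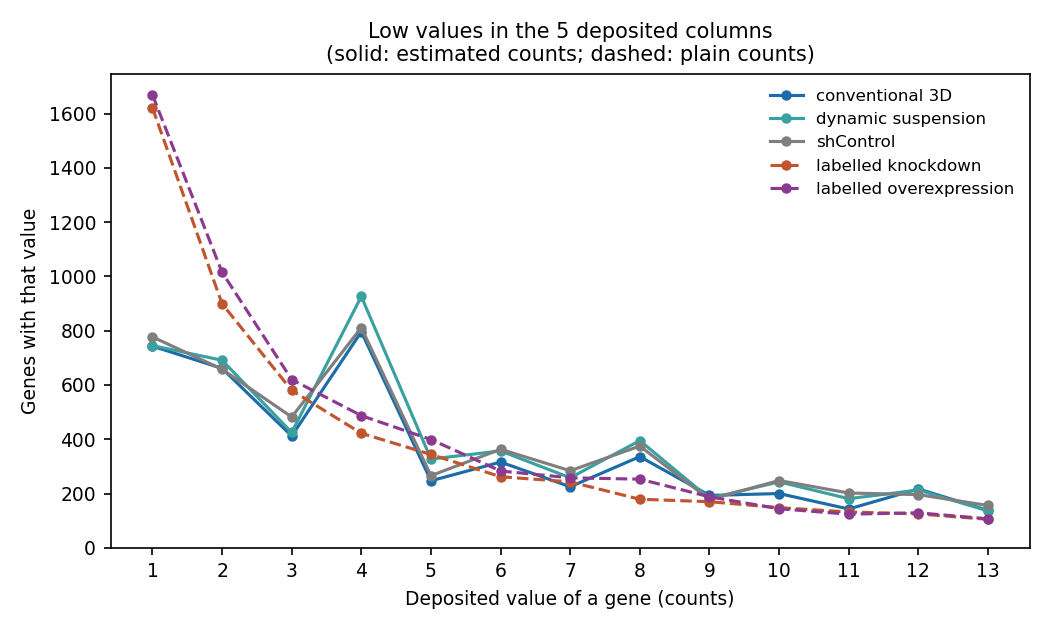
The number of genes (vertical axis) at each deposited value from 1 to 13 counts (horizontal axis) is plotted for the 5 libraries, with solid lines for estimated counts and dashed lines for plain counts. In the 3 solid lines more genes lie at 4 than at 3 (796 against 412 in conventional 3D culture), and in the dashed lines the number falls from 1 to 4.

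Hif1a, the targeted gene (ENSMUSG00000021109, GRCm38 chromosome 12, 73901375 to 73947530, plus strand, protein-coding), stood at 61.3 TMM-scaled CPM in shControl (95% Poisson counting interval 59.4 to 63.3) and at 95.1 CPM in the library labelled knockdown (90.3 to 100.1). This was 1.55-fold higher in the library labelled knockdown (log2 ratio 0.63, 95% counting interval 0.55 to 0.72), against its label. For this reason it is called the library labelled knockdown throughout, and no direction taken from it can be read as an effect of lower Hif1a. In the library labelled overexpression Hif1a was 384 CPM (375 to 394), 6.26-fold above shControl (log2 ratio 2.65, interval 2.59 to 2.71), in the direction of its label. Hif1a was also high in the cultures without a construct label, at 542 CPM in conventional 3D culture (535 to 548) and 390.5 CPM in dynamic suspension (386 to 395.5). Over shControl, the log2 ratio of Hif1a was 3.14 in conventional 3D culture and 2.67 in dynamic suspension.

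Epas1, which encodes HIF-2α (chromosome 17, 86753700 to 86833410), was 24.1 CPM in conventional 3D culture, 13.7 in dynamic suspension, 13.1 in shControl, 19.8 in the library labelled knockdown and 30.7 in the library labelled overexpression. Trp53, the gene of p53 (chromosome 11, 69580359 to 69591873), was 143 and 116 CPM in conventional 3D culture and dynamic suspension, 201 in shControl, 283 in the library labelled knockdown and 79.0 in the library labelled overexpression. Mdm2, the ubiquitin ligase that degrades p53 and is itself a p53 target (chromosome 10, 117688875 to 117710758), was 32.3, 57.7, 114, 82.8 and 89.3 CPM in the same order. Cdkn1a, the p53-induced cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), was 341, 434, 424, 489 and 586 CPM in that order.

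**Figure D2:**
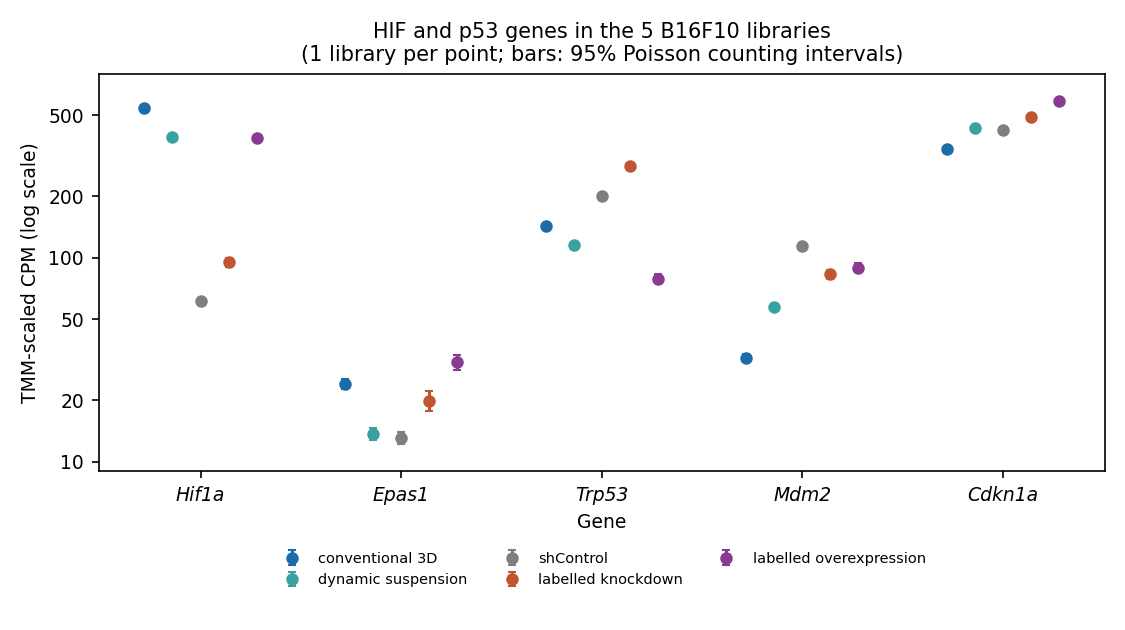
TMM-scaled CPM (vertical axis, log scale) of Hif1a, Epas1, Trp53, Mdm2 and Cdkn1a (horizontal axis) in each of the 5 libraries, 1 point per library, with 95% Poisson counting intervals as bars. Hif1a lies at 61.3 CPM in shControl and 95.1 CPM in the library labelled knockdown, and at 384 CPM or more in the other 3, while Trp53 is lowest in the library labelled overexpression at 79.0 CPM.

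Between the culture methods, cell cycle genes were lower, and interferon-response, immediate early and hypoxia-response genes were higher, in dynamic suspension than in conventional 3D culture. Of 30 measured genes of cell cycle and DNA replication, 24 were lower beyond 2-fold and 0 higher (median log2 ratio -1.83, percentile 0.0 among random lists of matched expression). Ccnb2, a mitotic cyclin, was 4.73 against 44.5 CPM (log2 ratio -3.22, 95% counting interval -3.41 to -3.05) and Plk1, a mitotic kinase, 6.36 against 57.0 CPM (log2 ratio -3.16, interval -3.32 to -3.01). Of 26 interferon-response and antigen-presentation genes, 15 were higher beyond 2-fold and 0 lower (median 1.14, percentile 100), with Ifit1, an antiviral RNA-binding protein, at a log2 ratio of 2.90, Oasl2 at 74.3 against 11.3 CPM and the chemokine gene Ccl5 at 107 against 19.2 CPM. Of 17 immediate early genes, 10 were higher and 3 lower (median 1.20, percentile 100), including Egr1 at 92.3 against 4.17 CPM, Fos at 91.4 against 7.25 CPM and Jun at 296 against 55.5 CPM.

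Hypoxia targets stood higher in dynamic suspension although Hif1a itself was 1.39-fold lower there (log2 ratio -0.47, interval -0.50 to -0.45). Of 29 HIF-1 and hypoxia targets outside glycolysis, 13 were higher and 4 lower beyond 2-fold (median 0.56, percentile 100), and of the 23 of own sequence 7 were higher and 4 lower (median 0.47, percentile 100). Hilpda, a lipid droplet protein, was 53.4 against 10.1 CPM, Ero1l, an endoplasmic reticulum oxidase, 1811 against 374 CPM, and Bnip3 (shared sequence), a mitophagy receptor, 640.4 against 157 CPM. Among 20 glycolytic targets, 3 were higher and 1 lower (median 0.30, percentile 100): the glucose transporter gene Slc2a1 (log2 ratio 1.59), Pfkl (1.49) and Pfkp (1.03) were higher and Slc2a3 lower (-1.06). Egln1, an oxygen sensor that marks HIF-1α for degradation, was 299 against 99.6 CPM and Vhl, its partner in that step, 112 against 49.4 CPM, among 8 HIF pathway components with a median of 0.05.

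Integrated stress response genes and unfolded protein response chaperones were also higher in dynamic suspension. Heat shock genes were not, with 1 of 14 higher and 0 lower. In the integrated stress response 9 of 20 genes were higher and 0 lower (median 0.26, percentile 99.8), led by Ddit3 (shared sequence, log2 ratio 3.73), Ppp1r15a (2.45) and Atf3 (2.24). Of 16 chaperones of the unfolded protein response, 6 were higher and 0 lower (median 0.54, percentile 100), with Hspa5, the main endoplasmic reticulum chaperone, at 1442 against 607 CPM. Only 10 of 72 histone genes were measured, the others lying below 1 CPM. Of these 10, 8 were higher (median 1.55, percentile 100), or 2 of the 3 of own sequence. The linker histone gene H1f0, for example, was at 713 against 213 CPM. The 80 ribosomal protein genes had a median of 0.06, which was percentile 99.9 of its random lists, with 0 higher and 1 lower beyond 2-fold.

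Extracellular matrix and mitochondrially encoded genes were lower in dynamic suspension. Of 19 matrix and mesenchymal genes, 9 were lower and 4 higher (median -0.66, percentile 0.0, but -0.25 and inside the random range without members under 10 CPM): the collagen genes Col3a1 and Col1a1 had log2 ratios of -2.46 and -2.43, whereas Col5a1 (2.22) and Spp1 (shared sequence, 2.89) were higher. Markers of fibroblasts moved with that group, with 5 of 8 lower and 0 higher (median -1.77, percentile 0.0), including Col1a2 at 8.16 against 35.2 CPM and Dcn at 3.16 against 8.66 CPM. The collagen genes Col1a1, Col1a2 and Col3a1 belong to both lists, and whether melanoma cells or other cells were their source is uncertain. Of the 13 mitochondrially encoded genes, 8 were lower (median -1.03, percentile 0.0). Mt-Co1 alone (shared sequence) took 2.91% of the dynamic suspension values and 7.57% of the conventional 3D values.

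Neither the p53 lists nor the stemness list stood apart between the culture methods. Of 31 p53 targets, 5 were higher and 4 lower (median 0.05, percentile 80.6), with Btg2 (log2 ratio 2.10) and Gadd45a (shared sequence, 1.40) higher and Tigar (-1.72) and Phlda3 (-1.68) lower. Of 17 regulators of p53, 0 passed 2-fold in either direction (median 0.05). Of 25 stemness markers, 11 lay below 1 CPM, among them Pou5f1, Sox2, Nanog, Prom1, Aldh1a1 and Abcb5, and of the 14 measured, 2 were higher and 3 lower (median 0.19, percentile 88.2). Nes, an intermediate filament of neural stem cells, was 47.8 against 19.7 CPM, Abcb1b, a drug efflux pump, 3.08 against 19.5 CPM, Myc 16.8 against 36.0 CPM and Cd44 286 against 484 CPM. The other lists lay within the range of random lists: melanocyte differentiation (median -0.33), NRF2 antioxidant genes (-0.32), nuclear oxidative phosphorylation (-0.26), YAP and TEAD targets (-0.14), cholesterol synthesis (-0.07), NF-kappaB inflammatory genes (-0.07), heat shock genes (-0.02), lysosome and autophagy (0.01) and apoptosis regulators (0.02). Of the markers of other cell types, 1 of 12 immune genes was measured, Cd68 at 13.2 against 12.4 CPM, and 1 of 8 endothelial genes, Vwf at 1.04 against 10.7 CPM, with 0 of 10 epithelial and 0 of 6 erythroid genes. Within the melanocyte list, Gpnmb was higher (log2 ratio 2.13) and Oca2 (-1.64), Pmel (-1.16) and Slc24a5 (shared sequence, -1.65) were lower.

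In all, 833 of 12875 genes were higher and 989 lower beyond 2-fold in dynamic suspension. The highest were Dhrs3, a retinaldehyde reductase (211 against 0.977 CPM, log2 ratio 7.70, interval 7.36 to 8.18), Sema7a (5.32), Plekhb1 (4.82), Bmyc (shared sequence, 4.73), Gbp6 (shared sequence, 4.57), Egr1 (4.46), Rarb (shared sequence, 4.19) and Gsta3 (4.02). The lowest were Myom1, a sarcomere protein (2.67 against 247 CPM, log2 ratio -6.52, interval -6.77 to -6.31), Lmo2 (-6.51), Cort (-4.66), Adam23 (-4.38), Smtnl1 (-4.28), Asb10 (-4.09), Brca1 (-4.07) and Eno3 (-3.88). Scaling by total counts in place of TMM moved all ratios up by 0.189 and turned the split to 1120 higher and 706 lower, so negative medians nearer 0 than that turn positive.

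Against shControl, the library labelled knockdown had higher integrated stress response, cholesterol synthesis and YAP target genes, and lower interferon-response and pigment-cell genes. In the integrated stress response 10 of 20 genes were higher and 0 lower (median log2 ratio 1.10, percentile 100), with Chac1, a glutathione-degrading enzyme, at a log2 ratio of 2.55, Trib3 at 336 against 73.5 CPM and the amino acid transporter gene Slc7a5 at 918 against 316 CPM. Of 22 cholesterol synthesis genes, 11 were higher and 2 lower (median 0.97, percentile 100): Srebf2, the transcription factor of the pathway, was 544 against 187 CPM (log2 ratio 1.55), whereas Fdps (shared sequence) was 3.22 against 125 CPM. Of 26 interferon-response genes, 13 were lower and 0 higher (median -1.34, percentile 0.0), including the chemokine gene Cxcl10 at 11.4 against 35.8 CPM and B2m, the light chain of class I antigen-presenting molecules, at 160.3 against 409.6 CPM. Of 19 melanocyte genes, 7 were lower and 0 higher (median -0.89, percentile 0.0): Trpm1, a melanocyte ion channel, was 15.6 against 339 CPM, Tyr, the rate-limiting enzyme of melanin synthesis, 364 against 942 CPM, and Mitf, the lineage's master regulator, 139 against 314 CPM. The rise of cholesterol genes over shControl was not particular to this library. Their median was also higher in conventional 3D culture (0.81), dynamic suspension (0.89) and the library labelled overexpression (0.90).

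Hypoxia targets were not lower in the library labelled knockdown than in shControl, and Hif1a was higher. Of 20 glycolytic targets, 3 were higher and 0 lower beyond 2-fold (median 0.52, percentile 99.7), with the lactate exporter gene Slc16a3 at 104 against 39.1 CPM and Ldha, lactate dehydrogenase, at 2212 against 1101 CPM, while Eno2 had a log2 ratio of -0.98. Of 29 other hypoxia targets, 6 were higher and 3 lower (median 0.22, percentile 87.3), with Ndrg1 (log2 ratio 1.61), Ccng2 (1.34), Ak4 (1.20) and Ddit4 (1.11) higher. The 8 HIF pathway components had a median of 0.37 with 0 beyond 2-fold.

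The p53 lists did not stand apart from random lists here. Trp53 was 1.41-fold higher (log2 ratio 0.49, interval 0.44 to 0.54) and Mdm2 1.38-fold lower (-0.46, interval -0.55 to -0.38). Of 31 p53 targets, 2 were higher and 3 lower (median 0.00, percentile 35.6): Bbc3, the pro-apoptotic PUMA gene (log2 ratio 1.81), and Rps27l (1.27) were higher, and Trp53inp1 (-1.19) and Ccng1 (-1.07) lower. Among p53 regulators (median 0.04) Hipk2, a kinase of p53, was 160 against 22.2 CPM and Atr, a DNA damage kinase, 10.6 against 26.2 CPM. Of 14 stemness markers, 2 were higher and 1 lower (median 0.20, percentile 81.6): Notch1 (log2 ratio 2.33) and Itga6 (1.04) were higher and Bmi1 (shared sequence, -1.01) lower. Among the 30 cell cycle genes, E2f1 was higher (1.34) and Bub1 (-1.49) and Mki67 (-1.34) were lower beyond 2-fold (median 0.21, percentile 77.9).

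Of 15 YAP and TEAD targets, 5 were higher and 1 lower (median 0.62, percentile 99.8), with Ajuba (log2 ratio 1.22), Arhgef17 (1.21) and Tgfb2 (1.17) higher and Ccn2 (shared sequence, -2.74) lower. Chaperones of the unfolded protein response had a median of -0.48 (percentile 0.2), with 1 of 16 higher, Herpud1 (1.30), and 2 lower, Hsp90b1 (shared sequence, -2.53) and Dnajb9 (-1.14). The 19 matrix genes had a median of -0.46 (percentile 1.6), which turned to 0.26 when members under 10 CPM were left out. Fibroblast markers stood at a median of -1.64 (percentile 1.2), with Col1a2 at a log2 ratio of -2.32 and Pdgfrb, in the other direction, at 24.6 against 5.91 CPM. The 13 mitochondrially encoded genes had a median of -0.73 (percentile 0.2), led by mt-Atp8 (shared sequence, 2.23 against 1153 CPM), and this median was -0.08 among the 5 members of own sequence.

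In total, 1016 of 12639 genes were higher and 1974 lower beyond 2-fold in the library labelled knockdown. The highest were Cfap43 (34.8 against 0.682 CPM, log2 ratio 5.57, interval 5.22 to 6.17), Sorcs2 (4.63), Brms1 (shared sequence, 3.58), Fscn1 (3.54), mt-Rnr2 (a mitochondrial ribosomal RNA, 3.21), Kank4 (2.93), Mbp (2.92) and Hipk2 (2.84). The 8 lowest were all genes with shared sequence. Akap2 had 1 count against 28704, a ratio of 7101 with a counting interval of 1274 to 280485. Each of the others had 0 counts: by a floor of 3 counts, Raver1 was at least 601-fold lower, Hgs 539-fold, Rbm42 356-fold, Mrpl53 342-fold, Fam221b 328-fold, Cpne1 295-fold and Med10 265-fold. Among 9113 protein-coding genes of own sequence, a set chosen after the data were seen, 803 were higher and 718 lower. The share of higher genes thus went from 34.0% to 52.8%. These genes were not scaled anew, and their median log2 ratio was 0.122 against 0.006 over all genes. In that set the lowest were Wdr74 (4 counts against 2053, log2 ratio -6.73, interval -8.87 to -5.63), Cox17 (-5.45), Trpm1 (-4.43), Lgals3 (-3.61), Lcp1 (-3.56), Lif (-3.33), Mgarp (-2.93) and Uimc1 (-2.90).

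The library labelled overexpression had higher hypoxia-response and cholesterol synthesis genes and far lower cell cycle genes than shControl. Of 20 glycolytic targets, 8 were higher and 0 lower (median log2 ratio 0.86, percentile 100), with Aldoc, a glycolytic aldolase, at 143 against 8.88 CPM (log2 ratio 4.01, 95% counting interval 3.88 to 4.15), Slc16a3 at 258 against 39.1 CPM and Eno2 at a log2 ratio of 2.49. Of 29 other hypoxia targets, 13 were higher and 3 lower (median 0.93, percentile 100), among them Ero1l at 669 against 117 CPM and Ak4, a mitochondrial adenylate kinase, at 73.8 against 15.9 CPM. Of 30 cell cycle genes, 26 were lower and 0 higher (median -2.58, percentile 0.0), with Plk1 at 11.9 against 116 CPM and Birc5, the survivin gene, at a log2 ratio of -3.24. Of 22 cholesterol genes, 10 were higher and 1 lower (median 0.90, percentile 100): Insig1, the sterol sensor, was 497 against 59.5 CPM, and Fdps (shared sequence) was lower. These shifts were not particular to this library. Conventional 3D culture, without a construct label, had medians over shControl of 0.88 for glycolytic and 0.76 for other hypoxia targets. Its medians for cholesterol and cell cycle genes were 0.81 and -1.61. In dynamic suspension the same medians over shControl were 1.535, 1.527, 0.888 and -3.208 in that order.

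In the library labelled overexpression, 4 of 8 HIF pathway components were higher than in shControl and 0 lower (median 1.00, percentile 99.7). These were Hif1a, Egln1 (log2 ratio 1.49), Egln3 (1.41) and Epas1 (1.22). Trp53 was 2.55-fold lower (-1.35, interval -1.43 to -1.27), while Cdkn1a was 1.38-fold higher (0.47, interval 0.43 to 0.50) and Mdm2 1.28-fold lower (-0.35, interval -0.43 to -0.27). Of 31 p53 targets, 5 were higher and 3 lower (median 0.19, percentile 85.4), including Dcxr (1.71), Rrm2b (1.56), Phlda3 (1.41) and Cd82 (1.39), all higher. Of 17 p53 regulators, 3 were higher and 3 lower (median -0.21, percentile 20.3), with Mdm4, an inhibitor of p53, at 228 against 73.9 CPM, Hipk2 at 108 against 22.2 CPM and Chek1, a checkpoint kinase, at 5.24 against 42.6 CPM. Of 14 stemness markers, 3 were higher and 5 lower (median -0.54, percentile 7.6, but -0.61 and below the random range among the 13 of own sequence), with Kdm5b (1.65) and Notch1 (1.39) higher and Nes (-1.51) and Alcam (-1.41) lower.

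Integrated stress response genes were lower than in shControl, 7 of 20 with 0 higher (median -0.74, percentile 0.4), led by Atf5 (log2 ratio -2.23), Shmt2 (-2.20) and Psat1 (-1.86). NRF2 antioxidant genes were higher, 6 of 18 with 0 lower (median 0.61, percentile 99.5, but 0.57 and inside the random range among members of own sequence), with Nqo1 at 25.7 against 1.90 CPM and Gsta4 at 103 against 12.9 CPM. Immediate early genes had a median of 0.53 at the upper edge of the random range, and 0.40 inside it without members under 10 CPM, with 6 of 17 higher and 1 lower, Dusp1 leading at 38.6 against 6.93 CPM. Among the interferon genes (median 0.05) 7 were higher, including Rsad2 at 90.8 against 16.5 CPM, and 6 lower, including Cxcl10 at 1.43 against 35.8 CPM. Of 80 ribosomal protein genes, 23 were lower and 1 higher (median -0.72, percentile 0.0), or 5 and 1 of the 26 of own sequence (median -0.62). Of 19 matrix genes, 9 were lower and 1 higher (median -0.84, percentile 0.4, but -0.39 and inside the random range without members under 10 CPM), with Fn1, fibronectin, at 13.0 against 84.9 CPM. Of 8 fibroblast markers, 5 were lower and 1, Pdgfrb, higher. Col1a2 had 0 counts against 679, at least 61.7-fold lower by the floor of 3 counts, and the fibroblast median of -3.69 was -2.76 with genes at 0 set to that bound. In the pigment list (median -0.07), Oca2 was higher (2.58) and Gpnmb (-2.06), Mlana (-1.70) and Mlph (-1.31) lower. The mitochondrially encoded median of -1.07 turned to 0.41 among the 5 members of own sequence.

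In this comparison 2076 of 12881 genes were higher and 2594 lower beyond 2-fold. The highest were Malat1 (a long non-coding RNA, 1240.0 against 25.8 CPM, log2 ratio 5.58, interval 5.51 to 5.66), Cort (5.57), Hpse, the heparan sulfate-cleaving enzyme heparanase (5.29), mt-Rnr1 and mt-Tc (a mitochondrial ribosomal and transfer RNA, 4.88 and 4.86), Btn2a2 (4.45) and Myom1 (4.37). Of the 8 lowest, 7 were marked as shared sequence, Fam221b again narrowly, and mt-Ts1 is a mitochondrial transfer RNA. Akap2 and Gapdh-ps15 were at 1 count, Nme2 at 3 counts against 31329 (a ratio of 2848, interval 974 to 13810), and Raver1, Mrpl53, Fam221b, Med10 and mt-Ts1 at 0. Akap2 gave a ratio of 7827 (interval 1405 to 309172) and Gapdh-ps15 one of 1938 (348 to 76568). By the floor of 3 counts Raver1 was at least 662-fold lower, Mrpl53 377-fold, Fam221b 362-fold, Med10 292-fold and mt-Ts1 268-fold. Among 9215 genes of own sequence 1586 were higher and 1124 lower, a share of higher genes of 58.5% in place of 44.5%. Without new scaling, their median log2 ratio was 0.12 against -0.02 over all genes. In that set the lowest were Wdr74 (0 counts, at least 187-fold lower), Dhrs3 (log2 ratio -6.13), Krt80 (-5.65), Nppb (-5.48), Lif (-5.12), Cxcl10 (-4.60), Gxylt2 (-4.28) and Lgals3 (-4.19), and Pygm (4.19), Ache (4.09) and Mfng (4.03) joined the highest.

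Between the libraries labelled overexpression and knockdown, both plain counts, cell cycle and integrated stress response genes were lower and hypoxia and interferon genes higher in the former. Hif1a was 4.04-fold higher (log2 ratio 2.01, 95% counting interval 1.93 to 2.10). Of 30 cell cycle genes, 27 were lower and 0 higher (median -2.71, percentile 0.0), with Plk1 at 11.9 against 156 CPM and Foxm1, a mitotic transcription factor, at 24.0 against 300.3 CPM. Of 20 integrated stress response genes, 16 were lower and 0 higher (median -2.03, percentile 0.0), with Shmt2 at 80.6 against 930.3 CPM and Chac1 at a log2 ratio of -2.87. Of 29 other hypoxia targets, 10 were higher and 1 lower (median 0.77, percentile 100), including Ero1l at 669 against 122 CPM and P4ha1, a collagen prolyl hydroxylase, at 335 against 89.8 CPM. Of 20 glycolytic targets, 5 were higher and 0 lower (median 0.65, percentile 99.8), including Eno2 (log2 ratio 3.46), Aldoc (3.12), Pdk1 (1.81) and Slc16a3 (1.31). Of 26 interferon genes, 12 were higher and 2 lower (median 1.00, percentile 100), with Rsad2 at 90.8 against 9.52 CPM and Tap1, the peptide transporter of antigen presentation, at 13.7 against 2.69 CPM.

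Trp53 was 3.58-fold lower in the library labelled overexpression than in the library labelled knockdown (log2 ratio -1.84, interval -1.93 to -1.75). Even so, 9 of 31 p53 targets were higher and 3 lower (median 0.12, percentile 83.3), with Rrm2b (2.53), Trp53inp1 (2.36), Cd82 (1.92) and Polk (1.76) higher. Mdm4 (2.06) and Atr (1.83) were higher and Chek1 (-2.22) lower among the p53 regulators. Of 14 stemness markers, 1 was higher and 4 lower (median -0.43, percentile 9.0, but -0.65 and below the random range among the 13 of own sequence), with Nes at 24.1 against 120.0 CPM, Aldh1a3 at 2.68 against 11.2 CPM and Myc at 33.8 against 102 CPM. Pigment genes had a median of 0.37 (percentile 96.1, but 0.56 and above the random range without members under 10 CPM), 7 of 19 higher and 2 lower, among them Trpm1 at 252 against 15.6 CPM, Tyr at 1378 against 364 CPM and Dct at 13722 against 4345 CPM. Of 80 ribosomal protein genes, 25 were lower and 1 higher (median -0.85, percentile 0.0), or 6 and 0 of the 26 of own sequence (median -0.80). Unfolded protein response chaperones (median 0.47, percentile 98.6) and immediate early genes (0.68, percentile 99.2) stood above their random lists, and fibroblast markers below (-1.08, percentile 0.4). Each of these came to lie inside the range in an alternative: the chaperones among genes of own sequence (0.33), and immediate early genes (0.47) and fibroblast markers (-0.96) without members under 10 CPM. The median of the mitochondrially encoded genes, 0.70 (percentile 99.4), turned to -0.46 among the 5 members of own sequence. In all, 2155 of 12305 genes were higher and 1825 lower beyond 2-fold, and among genes of own sequence 1551 and 1263 of 9195.

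**Figure D3:**
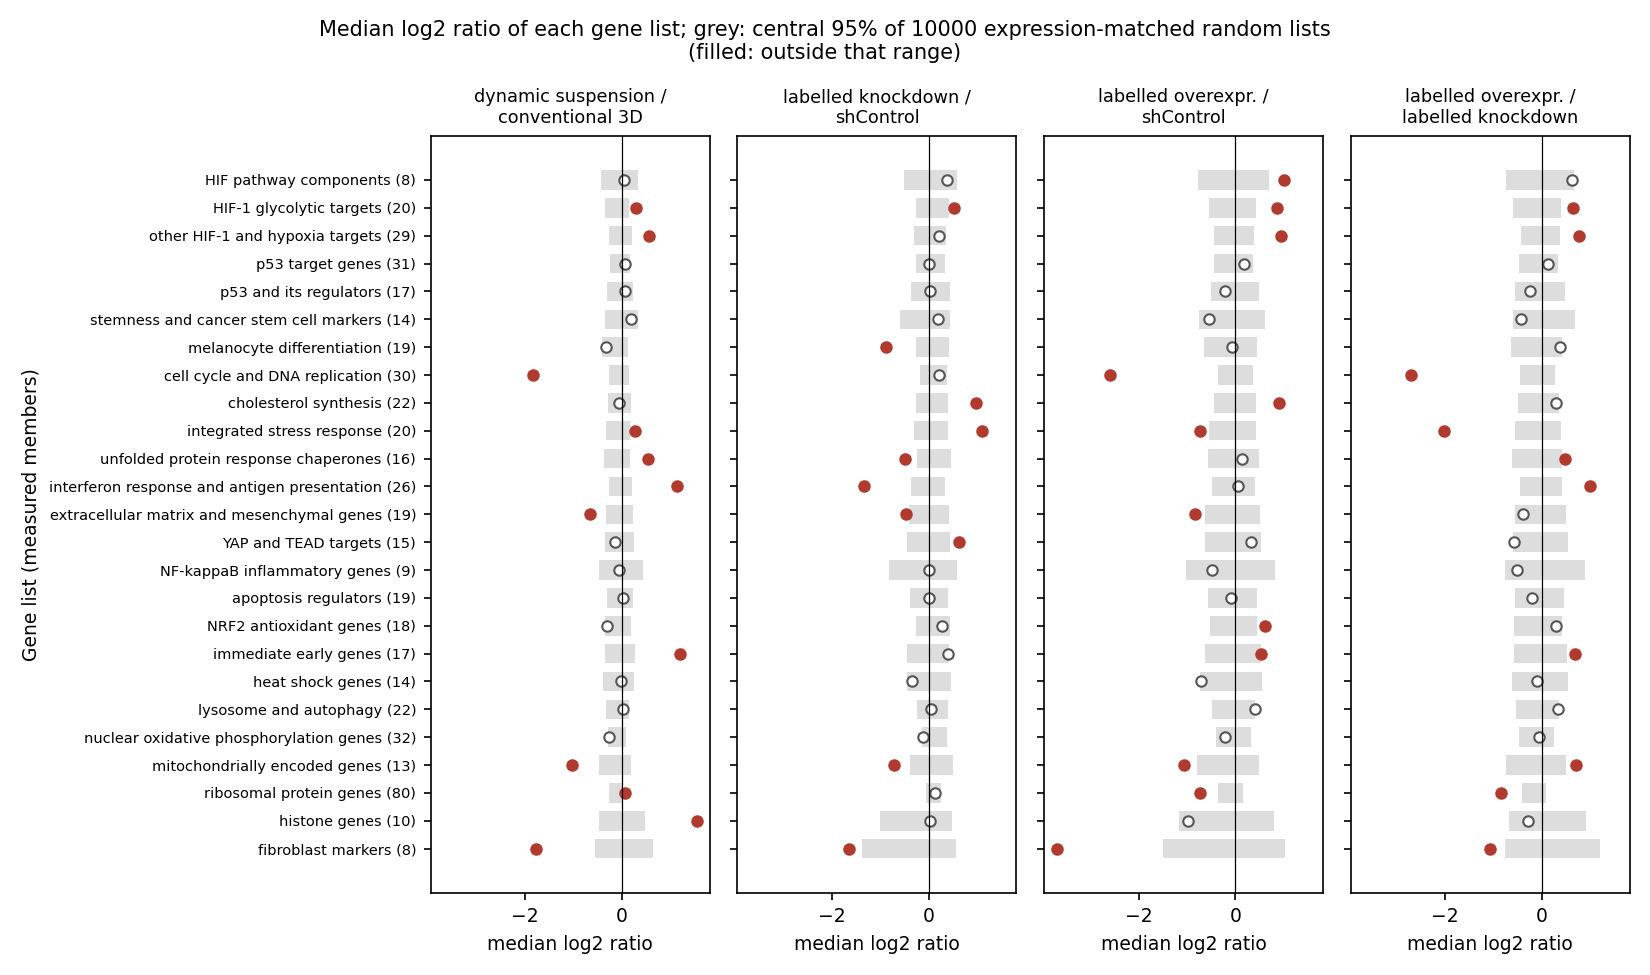
Median log2 ratio (horizontal axis) of each gene list with at least 8 measured members (vertical axis, number of measured members in parentheses) in the 4 planned comparisons, with grey bars for the central 95% of 10000 random lists of matched expression and filled points outside that range. Cell cycle genes lie far below the bars in 3 panels (-1.83, -2.58 and -2.71) and inside the bar for the library labelled knockdown over shControl (0.21).

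Few genes moved in opposite directions in the libraries labelled knockdown and overexpression when each was set against shControl. The genes with the largest opposite ratios were Tg, the thyroglobulin gene, with log2 ratios of 2.72 in the library labelled knockdown and -3.77 in the library labelled overexpression, and Prkcq, a T-cell-type protein kinase C, at 307 CPM in the library labelled knockdown, 79.9 in shControl and 23.2 in the library labelled overexpression. Slc35f1 and Gsdmc (shared sequence) went the same way. Ano3, a membrane protein of the anoctamin family, was 3.81, 17.8 and 94.3 CPM in that order, Ecm1, an extracellular matrix glycoprotein, 3.67, 16.9 and 69.1 CPM, and Cdhr4 (shared sequence), Ablim1 and Pqlc3 went this way too. Of 12432 genes tested in both, 93 were lower in the library labelled knockdown and higher in the library labelled overexpression, and 50 the reverse, against 274.6 and 195.9 for independent lists. In the same direction 433 were higher and 1176 lower in both, against 132.6 and 405.7 for independent lists. Among 9021 genes of own sequence the 4 counts were 74, 40, 335 and 200, against 113.3, 94.9, 121.2 and 88.6. Simulated unchanged libraries against the same shControl gave means of 0.0, 0.0, 0.03 and 0.08 over all genes. Across genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.732 (simulated 0.231) and a covariance of 1.666 (simulated 0.0045). For genes of own sequence r was 0.381 (simulated 0.225) and the covariance 0.344 (simulated 0.0031). Both comparisons use 1 shared control, which cannot be split, and the same 2 kinds of column. Part of the excess may come from these. The simulations hold counting error only and cannot show how large that part is.

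Over all 10 pairs of libraries, the library labelled overexpression lay nearest to conventional 3D culture and the library labelled knockdown nearest to shControl. Among genes of own sequence, 10.1% of 9213 were beyond 2-fold between the library labelled overexpression and conventional 3D culture (Spearman rho across genes 0.956), the smallest share of the 10 pairs, against 29.4% with shControl. The library labelled knockdown differed from shControl in 16.7% and from dynamic suspension in 34.5%. Dynamic suspension and conventional 3D culture differed in 13.6%, and each differed from shControl in 26.9% and 27.2%. Over all genes, the smallest share was that between dynamic suspension and conventional 3D culture, 14.2%, and the library labelled overexpression differed from conventional 3D culture in 18.0%.

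**Figure D4:**
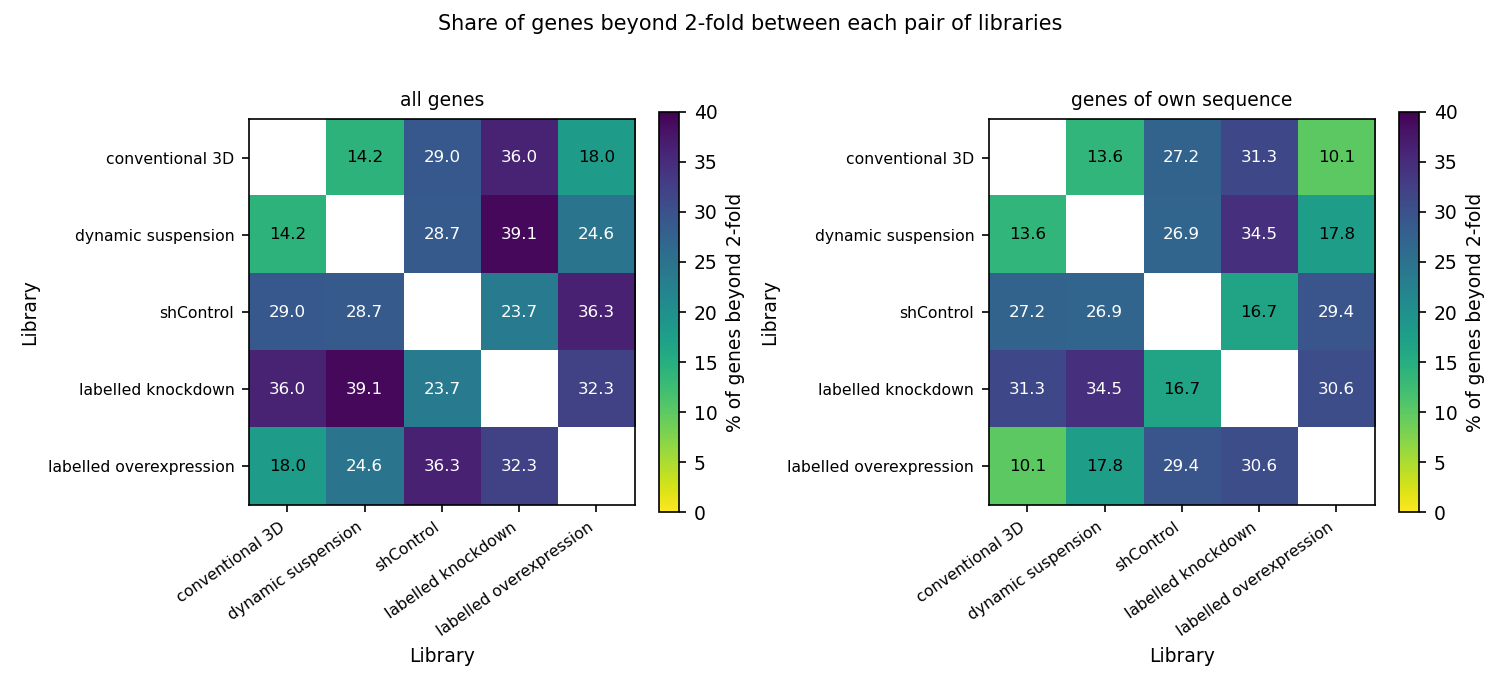
The percentage of genes beyond 2-fold (colour and printed value) is shown for each pair of the 5 libraries (both axes), over all genes on the left and genes of own sequence on the right. On the right the smallest value is 10.1%, between the library labelled overexpression and conventional 3D culture, and the largest 34.5%, between dynamic suspension and the library labelled knockdown.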

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

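No paired analysis was possible because each group carries only replicate number 1, and leaving out a library is not possible with 1 library per group. All 8 counts of genes beyond 2-fold stayed within 1.5 times under DESeq2 size factors, total counts, prior counts of 0.5 and 8, and, chosen after seeing the data, estimated counts divided by 4. Counts below are higher/lower for dynamic suspension over conventional 3D culture, then the libraries labelled knockdown and overexpression over shControl, then overexpression over the library labelled knockdown, and limits on level or size change them by construction. No CPM filter gave 2484 and 2227, 1652 and 3270, 3449 and 3989. At least 10 CPM gave 372 and 472, 645 and 906, 1255 and 1527, and 1239 higher in the last. A 1.5-fold limit gave 1844 and 2169, 2558 and 3176, 3448 higher for overexpression, and 3392 and 3289. A 4-fold limit gave 207 and 273, 147 and 834, 615 and 1171, 641 and 455. Genes of own sequence, fewer by construction, gave 515 higher, 718 lower and 1124 lower for the first 3 comparisons. With the dynamic suspension library as reference, chosen after seeing the data, 2197 were higher in the library labelled knockdown and 1673 lower in the library labelled overexpression, and the cause was not tested. Genes lower in the library labelled knockdown and higher in that labelled overexpression, the reverse, higher in both and lower in both were 160, 81, 732 and 2100 with no filter, 38, 28, 220 and 486 at 10 CPM, 364, 258, 1165 and 1831 at 1.5-fold and 4, 2, 71 and 641 at 4-fold, with 200 lower in both of own sequence. Hif1a moved to -0.283 and 2.723 under total counts in dynamic suspension over conventional 3D culture and overexpression over shControl, by the scaling itself. Of the list medians, 573 kept their side of the random range, some near 0 with a change of sign, 12 came to lie outside it, 12 inside and 3 reversed: matrix genes in the library labelled knockdown (0.257 at 10 CPM, fewer members), and mitochondrially encoded genes of own sequence over shControl (0.408) and over the library labelled knockdown (-0.456) in the library labelled overexpression, which keep 5 members. Histone genes of own sequence (3 members) in overexpression over shControl went from -0.97, inside the range, to 1.60, outside it, and over the library labelled knockdown from -0.29 to 1.74 (1.64 at 10 CPM). Matrix genes at 10 CPM moved inside the range for dynamic suspension (-0.248) and overexpression over shControl (-0.388). Of the ratios of named genes 1808 stayed within their intervals and 156 moved. The lower sums of values in the libraries labelled knockdown and overexpression (14803426 and 15393189) limit genes under 1 CPM there. As the kinds of column differ, these sums do not show how far sequencing depth differed.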

Other observations

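Dynamic suspension against shControl, both estimated counts and not a planned comparison, had higher interferon and hypoxia genes. Of 26 interferon-response genes, 25 were higher and 0 lower (median log2 ratio 3.26, percentile 100), with Oasl2 at 74.3 against 1.02 CPM and Usp18 at 81.9 against 1.88 CPM. Of 20 glycolytic targets 14 were higher and 0 lower, and of 29 other hypoxia targets 20 were higher and 3 lower (median 1.53). Of 30 cell cycle genes 27 were lower and 1 higher (median -3.21). Of 31 p53 targets 9 were lower and 3 higher (median -0.37, percentile 2.8), Pidd1 being 3.48 against 36.2 CPM. Conventional 3D culture differed from shControl in the same directions. There 21 of 26 interferon genes were higher and 1 lower (median 2.31). Glycolytic targets had 10 of 20 higher and 0 lower, and other hypoxia targets 11 of 29 higher and 1 lower. Targets of p53 had 10 of 31 lower and 3 higher (median -0.71).

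The library labelled overexpression, against conventional 3D culture, had lower interferon genes, 19 of 26 with 0 higher (median -2.52), and lower NF-kappaB genes, 7 of 9 with 0 higher (median -1.50). Of 31 p53 targets 13 were higher and 0 lower (median 0.78, percentile 100). Fibroblast markers were lower too, 6 of 8 (median -5.52, or -4.70 with genes at 0 set to the bound of 3 counts), as were 12 of 13 mitochondrially encoded genes (median -1.62). Here Hif1a was 384 against 542 CPM. Glycolytic targets stood close, with 2 of 20 higher and 0 lower (median 0.09, percentile 96.5). Other hypoxia targets had 4 of 29 higher and 3 lower (median 0.22, percentile 98.9, or 92.7 among those of own sequence). This comparison crosses the kinds of column. The library labelled knockdown, against dynamic suspension and again across the kinds of column, had lower Hif1a (95.1 against 390.5 CPM) and lower hypoxia targets, and its largest shifts were in other lists: 26 of 26 interferon genes were lower (median -4.69) and 28 of 30 cell cycle genes higher (median 3.47). Of 20 glycolytic targets 9 were lower and 1 higher (median -0.88, percentile 0.1), and of 29 other hypoxia targets 17 were lower and 3 higher (median -1.41, percentile 0.0).

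All tests below were chosen after the result had been seen. The first pattern is a set of 48 genes at 5 CPM or more in the conventional 3D, dynamic suspension and shControl libraries and at 2 counts or fewer in both libraries labelled knockdown and overexpression, such as Akap2 and Raver1. Of these, 45 (93.8%) overlap another gene or share its sequence, against a median of 22.9% and an upper limit of 35.4% in 1000 draws of genes of matched expression, as a difference in how reads of such genes were counted would give. Lower depth is excluded, since the smallest count expected was 103.3 and the median 344.9. The limit of 5 CPM that chose the genes already ensured high expected counts, so this could not have come out otherwise. The other 3 genes are of own sequence and stay unexplained, and no biological explanation was tested.

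The second pattern is Hif1a, higher in the library labelled knockdown (95.1 CPM) than in shControl (61.3 CPM). If the 2 labels were exchanged, hypoxia targets should be higher in the library labelled knockdown. Glycolytic targets lay at percentile 99.7 but other hypoxia targets at 87.3, which leaves this open. A rise of glycolytic targets over shControl was also seen in conventional 3D culture (median 0.88), dynamic suspension (1.535) and the library labelled overexpression (0.86). Exchanges with other libraries were not tested, although the column of the library labelled knockdown is headed B16F10, the bare name of the line. If the kinds of column caused this difference in Hif1a, the Hif1a ratio should be ordinary among 7449 genes of own sequence. It lay at percentile 79.4, which leaves this open too. That Hif1a is lower where cell cycle genes are higher, a biological explanation for its low level in shControl and the library labelled knockdown, stays open. Both were lower in dynamic suspension than in conventional 3D culture (Hif1a log2 ratio -0.472), but over shControl the cell cycle medians were -1.61, -3.21 and -2.58 in conventional 3D culture, dynamic suspension and the library labelled overexpression, where Hif1a was higher. Hif1a protein was not measured, and a knockdown seen in protein alone may exist.

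The third pattern is fibroblast genes such as Dcn and Col3a1. They were present in the conventional 3D, dynamic suspension and shControl libraries and at or near 0 in the other 2. Not all markers follow it: Col1a1 was 5.78 CPM in the library labelled knockdown, and Pdgfrb was higher than in shControl in both. Of 8 fibroblast markers, 3 were lower and 2 higher than in shControl in the library labelled knockdown. In the library labelled overexpression 5 were lower and 1 higher. The lowest level of Col1a1, Col1a2 and Col3a1 in the 3 libraries was 4.72 CPM, all above Dcn. Xist, from the inactive X chromosome of female cells, and Eif2s3y, from the Y chromosome, both had counts in the same 3 libraries (183, 140 and 111 for Xist, 27, 18 and 15 for Eif2s3y), so RNA from other mouse cells or samples could be part of them, as a hypothesis. Both were at 0 in the other 2, where the absence of Eif2s3y says little at its low level. Lower depth is excluded, since 38.1 Dcn counts were expected and 0 were seen in each of the 2 libraries. No biological explanation was tested.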
